A study of Arabidopsis thaliana with 6 samples.

How the data were processed

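RNA was measured in 6 Arabidopsis root tip libraries, 3 control and 3 bleomycin, which the design text calls biological replicates. Per the labels' protocols the libraries were prepared with a stranded mRNA kit. Per the submitters' processing notes CASAVA and Salmon 0.7.2 were used. The settings, the annotation, the genome build and whether Salmon used the strand are not given in the sources used here, so no coordinates are given. The deposited tables hold 1 row per transcript, with estimated counts and TPM values, per the file headers, for 90219 transcripts in each library. Effective lengths were identical in all 6 tables.

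The estimated counts were summed per locus and rounded to whole numbers. The 37686 nuclear and organelle gene loci were analysed, and 31189 transposable element loci were left out of the main comparison. TPM values were used only to weight transcript lengths for an alternative offset. Gene symbols and products came from the TAIR10.1 annotation by locus identifier, which matched 18891 of the 18915 genes tested, and this annotation was also used to find overlapping genes. Because strand use is not stated, the assignment of reads between overlapping genes is uncertain. Among the genes named, this concerns YSL2, HTB9, MIR408, SMR5, IAA5, EXP18, CYCD6;1, KN, CSD1, VPE1, RHS19, FRO3, MCM7, KU70, CKX5, ARR9, LOG4, 3xHMG-box2, ACL5, AT3G20360 and ENODL13. FRO4 and FRO5 are similar neighbouring genes, so the split of reads between them is uncertain.

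Reads assigned to genes came to 16233317, 17558541 and 15389376 in control replicates 1 to 3 and 17073467, 15767115 and 15760250 in bleomycin replicates 1 to 3. The 10 most abundant genes held 3.00% to 3.31% of gene reads. Ribosomal RNA loci held 0.288% to 0.523%, organelle genes 0.0225% to 0.0408% and transposable elements 0.119% to 0.145% of reads. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 4.19 to 9.49, so no library was counted as a duplicate. Counting intervals, at 95% and from exact binomial limits, and floors of 3 counts over a group cover counting error only. The floor was 0.0623 CPM for the control group.

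Counts were normalized by TMM, filtered with filterByExpr and tested, two-sided, with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The biological coefficient of variation was 8.84%. Standard errors are the log2 fold change divided by the square root of F. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. There were 15 pathway and 6 cell type lists with 366 entries, all matched to a locus in the tables.

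The rule for named genes took the 8 largest rises and 8 largest falls among called genes whose groups do not overlap and whose mean is at least 5 CPM in a group, up to 4 called members of each list by size of change, and always ERF115, CYCB1;1, SMR5, SMR7, BRCA1, WOX5, SOG1, PSK5, TAA1, IAA2, GH3.3, PLT1 and PLT2. Some genes that the rule takes are not reported here. On simulated counts for 18769 genes, the test recovered 21 of 34 genes raised 1.5-fold, 34 of 34 raised 2-fold and 33 of 33 raised 4-fold, 20 of 31, 29 of 32 and 32 of 32 lowered by the same folds, and made 16 false calls among 198. The 198 calls also count called genes of the stem cell niche list, which was raised 1.5-fold too. All genes were simulated with the same dispersion and without pairing, so recovery of genes that vary more between replicates may be lower.

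The replicate numbers come from the labels, which do not say that a number marks a shared day. Deviations from the group means correlated at 0.188, 0.219 and 0.227 between libraries of the same number, across genes, and at -0.211 to 0.00315 between the others. Deviations within a group cancel out, so positive values for the same number push the others down and these are not separate evidence. The numbers were therefore taken as a possible pairing. The main fit had no block, and the block was an alternative. Alternatives were DESeq2 size factors, upper quartile scaling, other count filters, the replicate block, DESeq2 1.42.0, limma-voom, a test against a log2 change of 0.5, a transcript length offset and leaving out each library in turn. The fit of transposable elements together with the genes was added after seeing the data.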

Results

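Messenger RNA was sequenced from 0.2 cm root tips of Arabidopsis thaliana Col-0 seedlings, in 3 control and 3 bleomycin libraries. Bleomycin is a glycopeptide that breaks DNA strands. Seedlings were moved 7 days after sowing to medium with or without 0.5 µg/ml bleomycin, and the bleomycin samples were labelled with a treatment of 24 h. The comparison asks how the root tip transcriptome responds to DNA damage, with an interest in auxin and in the transcription factor gene ERF115 during stem cell regeneration. Reads assigned to genes ranged from 15389376 to 17558541 per library. Log2 CPM values of replicates correlated across genes with Pearson coefficients of 0.987 to 0.990, where genes are not independent replicates. The first principal component held 64.4% of the variance and separated the groups.

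DNA damage response transcripts were higher in bleomycin root tips. The cyclin-dependent kinase inhibitor gene SMR7 rose from 0.940 ± 0.341 CPM to 40.1 ± 3.24 CPM (SD, n = 3 per group), and the transcription factor gene NAC044 rose from 1.26 ± 0.409 CPM to 40.5 ± 3.16 CPM (SD, n = 3 per group). The repair gene BRCA1 rose from 16.4 ± 0.998 CPM to 129.7 ± 12.3 CPM (SD, n = 3 per group). The mitotic cyclin gene CYCB1;1, a known damage reporter, rose from 26.4 ± 2.99 CPM to 59.9 ± 1.80 CPM, a log2 fold change of 1.19 ± 0.085 (SE). SOG1, which encodes the transcription factor that relays the damage signal, measured 20.4 ± 0.617 CPM in controls and 19.6 ± 1.69 CPM with bleomycin (SD, n = 3 per group) and did not pass the test.

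Of 18915 genes tested, 3957 differed between the groups, 1989 higher and 1968 lower with bleomycin (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Changes of 2-fold or more were called for 599 genes that rose and 76 that fell, and changes of 4-fold or more for 234 that rose and 9 that fell. The groups did not overlap for 38.4% of genes, where chance gives 10%. With the replicate number as a block the count was 5964, with 3084 higher and 2880 lower, and 3949 of the 3957 genes kept their call. Without bleomycin replicate 1 the count was 2213, with 1245 higher, 968 lower and 46 lower by 2-fold or more, and without bleomycin replicate 2 it was 2558, with 1296 higher and 1262 lower.

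**Figure D1:**
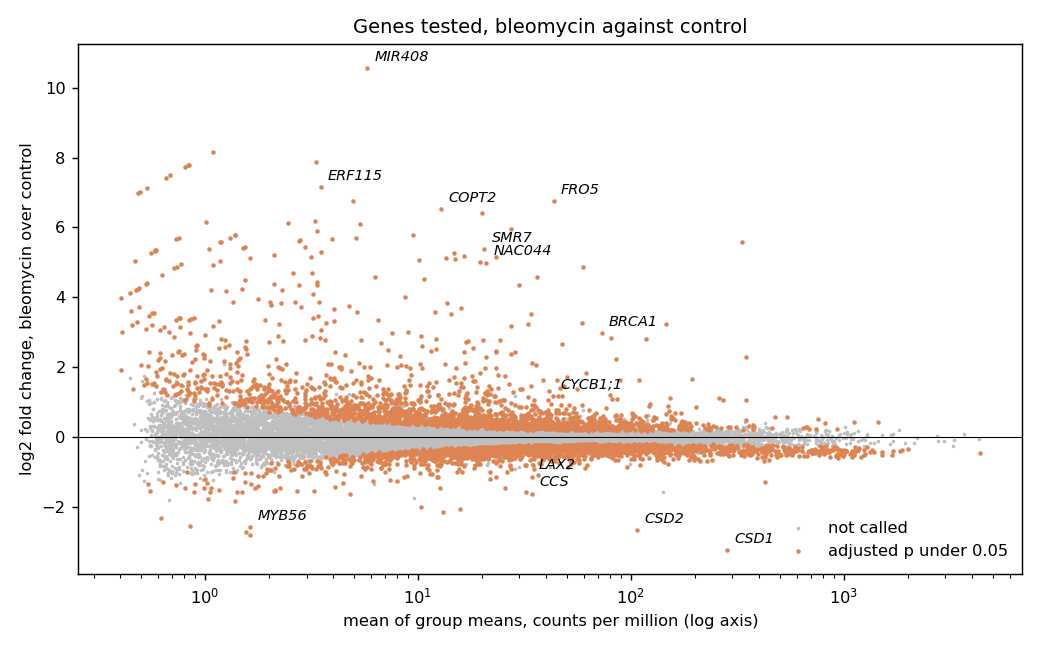
Log2 fold change of each of the 18915 genes tested, bleomycin over control, against the mean abundance in CPM (read counts scaled to a common library total) on a log axis. Each point is a gene, and called genes, at adjusted p under 0.05, are coloured. SMR7 lies at 5.38 and CSD1 at -3.22, and the fitted value of MIR408 depends on the prior count because the controls held 0 reads.

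Among the genes that rose most, the copper-regulated microRNA precursor gene MIR408 (AT2G47015) had 0 reads in the controls and 11.5 ± 1.23 CPM with bleomycin (SD, n = 3), at least 186-fold higher by reads summed over each group, against a floor of 3 counts over the control group. The RING/U-box gene AT2G25370 had 1 control read and ERF115 had 2, with ratios of 319.9 (95% counting interval 57.0 to 12674) and 167 (46.0 to 1387). The related factor gene ERF114 rose from 0.0869 ± 0.104 CPM to 9.87 ± 1.61 CPM, and the RAD3-like helicase gene AT1G20750 rose from 0.447 ± 0.184 CPM to 39.7 ± 7.49 CPM (SD, n = 3 per group). The ferric reductase gene FRO5 rose from 0.781 ± 0.178 CPM to 86.0 ± 18.1 CPM, and the copper transporter gene COPT2 rose from 0.269 ± 0.0901 CPM to 25.4 ± 2.07 CPM (SD, n = 3 per group). SMR5, another cyclin-dependent kinase inhibitor gene, rose from 0.0787 ± 0.0882 CPM to 6.51 ± 1.40 CPM (SD, n = 3 per group).

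Among the genes that fell most were CSD1 and CSD2, which encode copper/zinc superoxide dismutases. CSD1 fell from 513 ± 17.8 CPM to 55.1 ± 10.1 CPM, and CSD2 fell from 185 ± 10.3 CPM to 29.4 ± 1.04 CPM (SD, n = 3 per group). CCS, their copper chaperone gene, fell with a log2 fold change of -1.61 ± 0.10 (SE). ATGSTF13, a glutathione S-transferase gene, and ENODL13, an early nodulin-like gene, fell with log2 fold changes of -2.13 ± 0.23 and -2.04 ± 0.37 (SE). The asparaginase gene ASPGB1 fell from 16.6 ± 2.51 CPM to 4.16 ± 0.598 CPM (SD, n = 3 per group). The CTP synthase gene AT4G20320 and the TRAF-like gene AT3G20360 fell with log2 fold changes of -1.56 ± 0.085 and -1.61 ± 0.38 (SE). AT3G20360 lost its call (edgeR quasi-likelihood Benjamini-Hochberg adjusted p in brackets) without control replicate 2 (0.0598), bleomycin replicate 2 (0.0801) or bleomycin replicate 3 (0.0616) and with no count filter (0.0580).

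**Figure D2:**
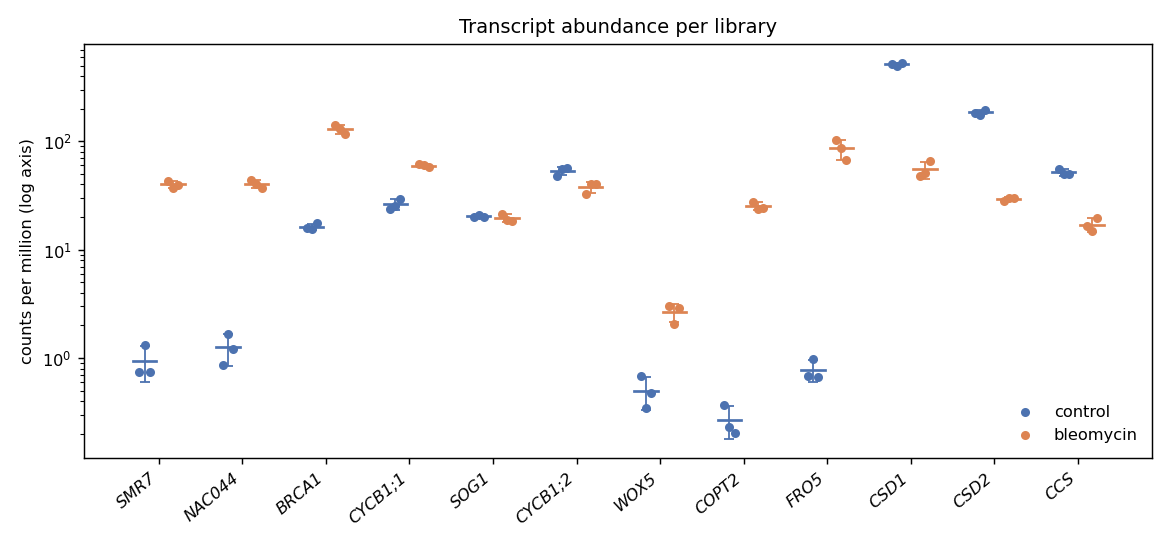
Abundance in CPM of 12 named genes in each library on a log axis. Points are the 3 control and 3 bleomycin libraries, horizontal lines are group means and error bars are the SD. SMR7 lies near 0.940 CPM in controls and 40.1 CPM with bleomycin, and CSD1 lies at 513 CPM and 55.1 CPM.

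Where a named gene lost its call, the settings named are all those tried except the test against a log2 change of 0.5, and adjusted p values in brackets are from edgeR unless DESeq2 or limma-voom is named. Gene lists were fixed before the data were examined, and the list tests below compare each list with all other genes by camera, with Benjamini-Hochberg adjustment over 21 lists. Of 24 DNA damage response transcripts tested, 21 rose and 0 fell, also 21 and 0 adjusted over the list alone, with a median log2 fold change of 1.69. The list was called by camera at an adjusted p of 1.37e-19, which was lost at an adjusted p of 0.145 with an estimated correlation. NAC085 rose by 5.64 ± 0.44 (SE) and SMR5 by 6.17 ± 0.43 (SE) on the log2 scale. Of 18 constitutive break repair and checkpoint genes, 0 rose and 2 fell, also 0 and 2 adjusted over the list alone, with a median of -0.17, and the list was called lower at a camera adjusted p of 0.00770 and not with an estimated correlation, at an adjusted p of 0.339. The end-joining gene KU70 fell, with a log2 fold change of -0.35 ± 0.080 (SE).

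Transcripts of G2 and M phase fell in part. Of 28 tested, 0 rose and 8 fell, also 0 and 8 adjusted over the list alone, with a median log2 fold change of -0.16 and a camera adjusted p of 0.00512, against an adjusted p of 0.888 with an estimated correlation. The mitotic cyclin gene CYCB1;1, which rose, was placed in the DNA damage response list and is not among the 28. Those that fell included 3xHMG-box2, a chromatin protein gene, -0.58 ± 0.085 (SE), and the mitotic cyclin genes CYCB1;2, -0.50 ± 0.10 (SE), and CYCA1;1, -0.47 ± 0.10 (SE). The cytokinesis syntaxin gene KN fell too, at -0.50 ± 0.14 (SE), a call lost (edgeR quasi-likelihood Benjamini-Hochberg adjusted p in brackets) without control replicate 2 (0.116), control replicate 3 (0.108), bleomycin replicate 1 (0.0922) or bleomycin replicate 2 (0.120) and with no count filter (0.0784). Fewer fell without control replicate 3, 5 genes and a camera adjusted p of 0.0799, and without bleomycin replicate 1, 3 genes.

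Of 23 DNA replication genes, 1 rose and 3 fell, or 1 and 1 adjusted over the list alone, with a median of -0.10 and a camera adjusted p of 0.0814. With the replicate block 5 fell and the list was called, at a camera adjusted p of 0.0220, against an adjusted p of 0.564 in that fit with an estimated correlation. The 0.564 says little, since the DNA damage response list itself had a camera adjusted p of 0.529 there. The ribonucleotide reductase gene RNR1 rose from 96.3 ± 2.63 CPM to 209.8 ± 12.6 CPM (SD, n = 3 per group). MCM7, CDT1A and PCNA1, which act in replication licensing and as the clamp, fell, with log2 fold changes of -0.27, -0.26 and -0.27. The number that fell was 0 without control replicate 2, bleomycin replicate 1 or bleomycin replicate 3 and 1 without control replicate 3, with DESeq2 or with limma-voom. The list was called without control replicate 1, at a camera adjusted p of 0.00773, without bleomycin replicate 2, at 0.0211, and without the count filter, at 0.0455. The call (edgeR quasi-likelihood Benjamini-Hochberg adjusted p in brackets) was lost for MCM7 without control replicate 2 (0.0827), bleomycin replicate 1 (0.115) or bleomycin replicate 3 (0.0777). It was lost for PCNA1 without control replicate 2 (0.126), control replicate 3 (0.0575), bleomycin replicate 1 (0.156) or bleomycin replicate 3 (0.123) and with the DESeq2 Wald test (0.0530) and with limma-voom (0.0511), and for CDT1A without control replicate 2 (0.146), control replicate 3 (0.0625), bleomycin replicate 1 (0.116), bleomycin replicate 2 (0.0795) or bleomycin replicate 3 (0.129) and with the DESeq2 Wald test (0.0605) and with limma-voom (0.0591).

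Of 19 cyclin-dependent kinase inhibitor genes, 5 rose and 4 fell, or 5 and 7 adjusted over the list alone. SMR4, SMR5 and SMR7, which rose, are also in the DNA damage response list, so they are counted in both lists. The median log2 fold change was -0.050 and the mean 0.58, so these differ in sign, and camera gave a rise at an adjusted p of 0.971. SMR4 rose by 1.46 ± 0.19 (SE) and SMR13 fell, at -1.01 ± 0.28 (SE), a call lost (edgeR quasi-likelihood Benjamini-Hochberg adjusted p in brackets) without control replicate 3 (0.0968), bleomycin replicate 2 (0.0990) or bleomycin replicate 3 (0.0668). The count of 4 was 1 without control replicate 3, 1 without bleomycin replicate 2, and 2 without bleomycin replicate 1 or with DESeq2.

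Wound and regeneration regulators were higher with bleomycin. Of 16 tested, 8 rose and 0 fell, also 8 and 0 adjusted over the list alone, with a median of 0.38 and a camera adjusted p of 6.22e-05, against an adjusted p of 0.145 with an estimated correlation. The correlation estimated for this list was -0.052, below the preset value, so it does not account for the lost call. ERF115 and ERF114 rose as given above. The phytosulfokine precursor genes PSK5 and PSK4, which encode peptide hormones, rose from 1.05 ± 0.266 CPM to 2.89 ± 0.258 CPM and from 4.62 ± 1.05 CPM to 9.85 ± 0.747 CPM (SD, n = 3 per group).

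Early auxin response transcripts rose as a list. Of 20 tested, 9 rose and 2 fell, or 11 and 2 adjusted over the list alone, with a median of 0.56 and a camera adjusted p of 0.00512, against an adjusted p of 0.170 with an estimated correlation. The estimate for this list was -0.0093, also below the preset value, so correlation does not account for the lost call. The auxin conjugating enzyme gene GH3.3 rose from 0.105 ± 0.128 CPM to 5.42 ± 0.577 CPM, and the auxin repressor genes IAA5 and IAA29 rose from 0.142 ± 0.0651 CPM to 2.86 ± 0.666 CPM and from 0.351 ± 0.0815 CPM to 2.24 ± 0.474 CPM (SD, n = 3 per group). IAA2 rose by 0.30 ± 0.076 (SE), a call lost without control replicate 1, at an edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 0.0696, or bleomycin replicate 3, at 0.0603. IAA20 fell, at -1.76 ± 0.37 (SE), and the number that fell was 1 when control replicate 1, control replicate 2 or any bleomycin library was left out, and with limma-voom.

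Auxin biosynthesis and transport genes moved in both directions. Of 12 biosynthesis genes, 1 rose and 3 fell, also 1 and 3 adjusted over the list alone, with a median of -0.084 and a camera adjusted p of 0.392. CYP79B3, an enzyme gene of the indole-3-acetaldoxime branch, fell from 5.91 ± 0.246 CPM to 2.23 ± 0.198 CPM (SD, n = 3 per group). TAR2 rose by 0.62, and YUC3 and CYP79B2 fell, at -0.47 and -0.41. The call (edgeR quasi-likelihood Benjamini-Hochberg adjusted p in brackets) was lost for TAR2 without control replicate 1 (0.0837), control replicate 3 (0.103), bleomycin replicate 1 (0.111) or bleomycin replicate 2 (0.0941) and with the DESeq2 Wald test (0.0806), for YUC3 without bleomycin replicate 1 (0.0759) or bleomycin replicate 3 (0.0625) and for CYP79B2 without control replicate 1 (0.0629), bleomycin replicate 1 (0.0894) or bleomycin replicate 2 (0.0819). TAA1, an enzyme gene of the main pathway, measured 0.31 ± 0.12 (SE) at an edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 0.0977, and was called with the replicate block, at 0.000841, and without bleomycin replicate 1, at 0.0435. With the block 2 biosynthesis genes were higher. The number that rose was 0 without control replicate 1, control replicate 3 or bleomycin replicate 2, or with DESeq2, and the number that fell was 1 without bleomycin replicate 1.

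Of 15 auxin transport genes, 2 rose and 3 fell, or 3 and 3 adjusted over the list alone, with a median of 0.11 and a camera adjusted p of 0.702. The kinase gene PID rose from 4.03 ± 1.67 CPM to 10.5 ± 1.22 CPM and the efflux transporter gene ABCB1 rose from 143 ± 13.7 CPM to 262 ± 20.6 CPM (SD, n = 3 per group). The influx carrier gene LAX2 fell from 46.8 ± 2.71 CPM to 21.5 ± 2.45 CPM, and the efflux carrier gene PIN4 fell from 72.7 ± 8.12 CPM to 47.6 ± 6.99 CPM (SD, n = 3 per group). With the block, and without control replicate 2, the number that rose was 4.

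In the other hormone lists, the counts were small. Of 17 cytokinin genes, 3 rose and 1 fell, also 3 and 1 adjusted over the list alone, with a median of 0.18 and a camera adjusted p of 0.538. They were CKX5 0.47, LOG7 0.38 and ARR9 0.24, and LOG4 -0.94, on the log2 scale. With the block 5 rose and 2 fell. The number that rose was 0 without control replicate 1 or bleomycin replicate 1 and 1 without control replicate 2 or bleomycin replicate 3, or with DESeq2, and the number that fell was 0 without control replicate 3, bleomycin replicate 1 or bleomycin replicate 2. The call (edgeR quasi-likelihood Benjamini-Hochberg adjusted p in brackets) was lost for LOG4 without control replicate 3 (0.0624), bleomycin replicate 1 (0.0861) or bleomycin replicate 2 (0.0777) and for LOG7 without control replicate 1 (0.0601) or bleomycin replicate 1 (0.0836). CKX5 lost it without control replicate 1 (0.171), control replicate 2 (0.108), bleomycin replicate 1 (0.0624), bleomycin replicate 2 (0.127) or bleomycin replicate 3 (0.124) and with the DESeq2 Wald test (0.0660). ARR9 lost it without control replicate 1 (0.149), control replicate 2 (0.0986), control replicate 3 (0.0766), bleomycin replicate 1 (0.195), bleomycin replicate 2 (0.0876) or bleomycin replicate 3 (0.0762) and with DESeq2 size factors (0.0579), with upper quartile scaling (0.0518), with no count filter (0.0692), with a filter of 10 counts in 3 libraries (0.05002), with the DESeq2 Wald test (0.163) and with limma-voom (0.0522). Of 10 jasmonate genes, 0 rose and 0 fell, also 0 and 0 adjusted over the list alone, with a median of -0.058 and a camera adjusted p of 0.676, and 1 rose and 0 fell by edgeR at an unadjusted p under 0.05, with 0 called by DESeq2 and by limma-voom and 2 higher without the count filter. Of 14 ethylene genes, 3 rose and 1 fell, or 3 and 2 adjusted over the list alone, with a camera adjusted p of 0.741. The ethylene median was 0.049 and the mean -0.068, which differ in sign. The F-box gene EBF1 rose by 0.42 ± 0.070 (SE), and the receptor gene ETR2 fell, at -1.11 ± 0.23 (SE). ACO1 rose by 0.57 ± 0.15 (SE), a call lost (edgeR quasi-likelihood Benjamini-Hochberg adjusted p in brackets) without control replicate 2 (0.0509), bleomycin replicate 1 (0.0537) or bleomycin replicate 3 (0.0676) and with the DESeq2 Wald test (0.0628). With the block, without the count filter, and without control replicate 1, 2 ethylene genes fell.

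Of 19 stem cell niche genes, 3 rose and 4 fell, or 3 and 7 adjusted over the list alone, with a median of -0.13 and a camera adjusted p of 0.0934. WOX5, the quiescent centre identity gene, rose from 0.501 ± 0.168 CPM to 2.65 ± 0.514 CPM (SD, n = 3 per group). MYB56, a regulator expressed around the niche, fell from 2.80 ± 0.307 CPM to 0.474 ± 0.262 CPM (SD, n = 3 per group), and RGF3, a root meristem growth factor gene, fell with a log2 fold change of -0.75 ± 0.10 (SE). CYCD6;1, a cyclin gene of formative divisions, rose by 0.80 ± 0.23 (SE), a call lost (edgeR quasi-likelihood Benjamini-Hochberg adjusted p in brackets) without control replicate 1 (0.0905), control replicate 2 (0.0574), bleomycin replicate 1 (0.0934) or bleomycin replicate 3 (0.0601) and with the DESeq2 Wald test (0.0630). The stem cell factor genes PLT1 and PLT2 measured log2 fold changes of -0.26 ± 0.10 and -0.12 ± 0.11 (SE) and did not pass the test, except PLT1 without control replicate 3, at an edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 0.0111. The number that rose was 1 without control replicate 1, control replicate 2, bleomycin replicate 1 or bleomycin replicate 3, or with DESeq2. Of 10 developmental cell death genes, 2 rose and 0 fell, also 2 and 0 adjusted over the list alone, with a median of 0.060 and a camera adjusted p of 0.430. The 2 were the ribonuclease gene RNS1, 2.78 ± 0.29 (SE), and VPE1, a vacuolar processing enzyme gene, 1.80 ± 0.31 (SE).

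Of 7 iron deficiency genes that passed the count filter, 3 rose and 0 fell, also 3 and 0 adjusted over the list alone, with a median of 0.46. The 3 were COPT2, FRO3, a ferric reductase gene, 0.64 ± 0.12 (SE), and PYE, a transcription factor gene, 0.46 ± 0.14 (SE). The list was called at a camera adjusted p of 0.0409 and not with an estimated correlation, at an adjusted p of 0.339. The call was also lost without control replicate 3, at an adjusted p of 0.120, without bleomycin replicate 2, at 0.101, and without the count filter, at 0.602. PYE lost its call (edgeR quasi-likelihood Benjamini-Hochberg adjusted p in brackets) without control replicate 1 (0.113), control replicate 2 (0.0762), bleomycin replicate 1 (0.0716) or bleomycin replicate 3 (0.129) and with the DESeq2 Wald test (0.0680) and with a transcript length offset (0.0723).

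Root hair transcripts were higher with bleomycin. Of 10 tested, 6 rose and 0 fell, or 8 and 0 adjusted over the list alone, with a median of 0.77 and a camera adjusted p of 0.000717, against an adjusted p of 0.612 with an estimated correlation. RHS19, a peroxidase gene, rose from 11.9 ± 4.01 CPM to 30.1 ± 1.86 CPM and MRH6 rose from 5.77 ± 0.892 CPM to 10.5 ± 0.856 CPM (SD, n = 3 per group). PRP3, a cell wall protein gene, rose from 26.4 ± 8.72 CPM to 55.7 ± 4.97 CPM (SD, n = 3 per group), but its edgeR quasi-likelihood Benjamini-Hochberg adjusted p was 0.0198 and 0.0991 with the replicate block, and its call was lost without control replicate 3 (0.0682), bleomycin replicate 1 (0.0706), bleomycin replicate 2 (0.0546) or bleomycin replicate 3 (0.0652) and with no count filter (0.0643). EXP18, an expansin gene, rose by 0.96 ± 0.22 (SE), a call lost (edgeR quasi-likelihood Benjamini-Hochberg adjusted p in brackets) without control replicate 1 (0.0587), control replicate 3 (0.0705), bleomycin replicate 1 (0.0797) or bleomycin replicate 2 (0.0710) and with no count filter (0.0738). Of 9 endodermis genes, 0 rose and 0 fell, also 0 and 0 adjusted over the list alone, with a median of 0.45 and a camera adjusted p of 0.242, and 1 rose and 0 fell by edgeR at an unadjusted p under 0.05, with 0 called by DESeq2 and by limma-voom. With the block 6 endodermis genes rose and the list was called, at a camera adjusted p of 0.0157, against an adjusted p of 0.782 in that fit with an estimated correlation. The 0.782 says little, since the DNA damage response list itself had a camera adjusted p of 0.529 there. Without control replicate 2 the endodermis list was called too, at a camera adjusted p of 0.00907, with 2 genes that rose.

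The other cell type lists were not called. Of 7 root cap genes, 0 rose and 1 fell, also 0 and 1 adjusted over the list alone, with a median of -0.016 and a camera adjusted p of 0.538, and the gene was FEZ, -0.84 ± 0.18 (SE). With the block 2 root cap genes fell. Of 11 xylem genes, 0 rose and 1 fell, also 0 and 1 adjusted over the list alone, and the gene was ACL5, -0.82 ± 0.10 (SE). Leaving out control replicate 2 gave 3 xylem genes that rose. The xylem median was 0.080 and its mean -0.048, which differ in sign, with a camera fall at an adjusted p of 0.808. Of 10 phloem genes, 1 rose and 1 fell, also 1 and 1 adjusted over the list alone, with a median of 0.062, a mean of -0.0036, which differ in sign, and a camera adjusted p of 0.985. OPS rose by 0.66 ± 0.13 (SE), and CVP2 fell, at -0.47 ± 0.14 (SE), a call lost (edgeR quasi-likelihood Benjamini-Hochberg adjusted p in brackets) without control replicate 2 (0.123), control replicate 3 (0.0575), bleomycin replicate 1 (0.125), bleomycin replicate 2 (0.0979) or bleomycin replicate 3 (0.0554) and with the DESeq2 Wald test (0.0886). The number of phloem genes that fell was then 0. Of 4 green tissue genes tested, 0 rose and 0 fell, also 0 and 0 adjusted over the list alone, with a median of 0.061 and a camera adjusted p of 0.924, with 0 also by edgeR at an unadjusted p under 0.05, by DESeq2 and by limma-voom, and 1 rose without control replicate 1.

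**Figure D3:**
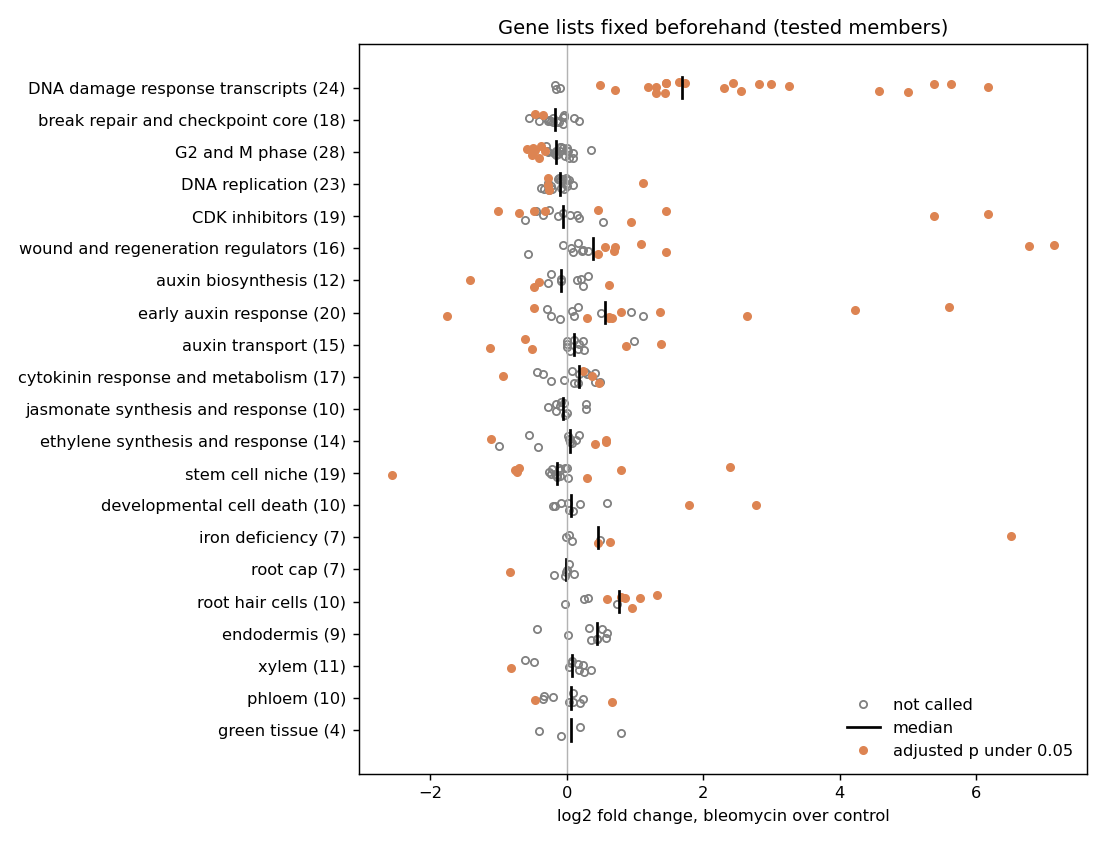
Log2 fold changes of tested members of the 21 gene lists, bleomycin over control, with the number tested in brackets. Filled points passed an adjusted p under 0.05, open points did not, and black bars are medians, from 1.69 for DNA damage response transcripts to -0.17 for break repair and checkpoint genes.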

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

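The tests of the iron deficiency list, of the antisense gene at MIR408, of root hair against other mature tissue transcripts and of library scaling, and the fit of transposable elements, were chosen only after the result was seen.

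Some annotated transposable elements, which the report does not use, were higher than in the controls, and the elements were not tested as a group. Fitted together with the genes, 12 of 207 tested elements were higher and 5 lower with bleomycin (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of the 18915 genes in that fit, 1964 were higher and 1954 lower, so in each direction a smaller share of elements than of genes was called. Many elements were at low abundance, where changes are harder to call. Transposable elements held 0.119% to 0.127% of reads in controls and 0.139% to 0.145% with bleomycin, a difference that was not tested. Whether the elements overlap genes was not examined. AT5TE45925 rose from 0.361 ± 0.213 CPM to 5.49 ± 1.78 CPM, AT2TE45520 rose from 2.36 ± 0.650 CPM to 8.86 ± 1.70 CPM and AT3TE60870 rose from 47.7 ± 8.19 CPM to 82.0 ± 5.49 CPM (SD, n = 3 per group).

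The first pattern was a set of copper-handling transcripts among the largest changes. Of 11 further transcripts known to rise when copper is short, listed before their values were seen, 7 passed the count filter and all 7 of these rose, with a median log2 fold change of 3.69, which is consistent with a copper limitation response, a hypothesis for which bleomycin's known binding of copper ions is a candidate cause that was not tested. The copper in the medium and the salt form of bleomycin are not given in the sources used here, so the chemistry of the medium stays open too. MIR398B, MIR398C, MIR397A and COPT6 did not pass the count filter, with 1, 11, 7 and 28 reads over all 6 libraries. Of the microRNA target genes listed to fall when copper is short, 2 laccase genes passed the filter and 0 were called lower. These 2 did not add to the hypothesis. CSD1, CSD2 and CCS were not in that list because their falls had already been noticed, with log2 fold changes of -3.22, -2.65 and -1.61. Overlap with other genes argues little for an artifact, since 3 of the 14 called copper transcripts (21.4%) overlap another annotated gene, and at MIR408 a constant share of the reads of the antisense gene AT2G47020 would give 155 control reads where 0 were found, although AT2G47020 rose too, from 26.8 ± 0.805 CPM to 96.4 ± 1.96 CPM (SD, n = 3 per group). A general iron or metal deficiency stays open, since the 5 tested iron deficiency genes other than COPT2 and FRO3 had a median of 0.072 while the whole list of 7 had 0.46, and a list that leaves out called genes excludes nothing.

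The second pattern was the higher level of root hair transcripts. If the treated segments held more mature tissue, endodermis and xylem transcripts would rise as much, and the root hair list exceeded these lists together by 0.55 ± 0.16 (SE, log2, n = 3 per group), at an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. It exceeded the xylem list by 0.72 ± 0.14 (SE), also at an exact two-sided permutation p of 0.1, which argues against more of all mature tissues. The argument is limited, since 3 xylem genes rose when control replicate 2 was left out. The root hair list was compared with endodermis too. It exceeded the endodermis list by 0.34 ± 0.25 (SE over libraries), or ± 0.10 within the 3 pairs of the same replicate number, from 0.14 to 0.46, where the smallest exact two-sided sign permutation p is 0.25. More mature tissue and a change in root hair cells cannot be told apart here because the first of these errors does not separate the lists and the endodermis list rose itself with the replicate block, at a camera adjusted p of 0.0157, though at 0.782 in that fit with an estimated correlation. That last value takes little from the endodermis rise, since the DNA damage response list was at 0.529 in the same camera test.

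The third pattern was that rises were larger than falls. Rises made up 88.7% of the called changes of 2-fold or more. The test planned first, with other scalings, moved the fold changes too little to decide whether scaling was the source (88.2% under DESeq2 size factors). A wrong scaling would shift all log2 fold changes alike, but at 10 CPM or more on average the 99th percentile lay 1.14 above the median and the 1st 0.62 below it, a difference of 0.52 (0.45 to 0.55 without any 1 library), so scaling is unlikely to be the whole source. Among genes that average at least 10 CPM over both groups, 146 rose and 21 fell by 2-fold or more, 87.4% rises. This argues against low average abundance as the source. Genes with few control reads, such as COPT2 with 13, can pass by their bleomycin level, so low control counts are not excluded. A biological asymmetry after bleomycin remains a hypothesis that may account for it, found and tested on the same data.

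The real split called 3957 genes, and the highest of the other 9 ways to split the 6 libraries into 3 and 3 called 2. The real split was 1 of 10 with as many, and 10 splits are too few for a share under 0.05. The 3 other splits that part every pair of replicate numbers called 0 genes each. All other splits put control and bleomycin libraries on both sides, so the treatment difference adds to the spread within each side. Few calls would follow from that alone, so these splits cannot show how many calls arise by chance.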

How the results depend on the processing

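The fit of transposable elements together with the genes was chosen only after the data were seen and left every gene count within 1.5 times. No gene called here was called in the other direction under any of the alternatives, this fit included. With the replicate block 5964 genes changed, 3084 of them higher, the DNA replication list was called at an adjusted p of 0.0220 and the endodermis list at 0.0157, against adjusted p values of 0.564 and 0.782 in that fit with an estimated correlation, TAA1 gained and PRP3 lost its call, and the block changed no other call of a list or named gene. By camera with the block and an estimated correlation no list was called, and the DNA damage response list was at 0.529. Those values therefore cannot decide about the 2 lists. Tested against a log2 change of 0.5, 522 genes changed, 474 higher and 48 lower, 37 of these lower by 2-fold or more, since that test asks for a larger change. Leaving out 1 library gave 2213 to 3851 changed genes, 1245 to 2011 higher, 968 to 1840 lower and 46 to 86 lower by 2-fold or more, with the lowest values without bleomycin replicate 1 (2213, 1245, 968 and 46) and 2558, 1296 and 1262 without bleomycin replicate 2, and fewer libraries were then tested. Changes of 2-fold or more that rose numbered 529 to 648 in those fits. With an estimated correlation none of the 7 called lists kept its call, at adjusted p values of 0.145 for DNA damage response and for wound and regeneration, 0.170 for early auxin response, 0.339 for break repair and for iron deficiency, 0.612 for root hair and 0.888 for G2 and M phase. The correlations estimated were 0.226 for DNA damage response, 0.0446 for break repair, 0.509 for G2 and M phase, 0.0637 for iron deficiency and 0.684 for root hair. They were -0.052 for wound and regeneration and -0.0093 for early auxin response, below the preset value, so correlation does not account for those losses. Whether correlation accounts for the other losses was not tested. With an estimated correlation no list was called, although 21 of 24 DNA damage response genes rose. A call lost in that test therefore says little about a single list. By fry the adjusted p was 6.24e-05 for DNA damage response, 3.75e-05 for wound and regeneration and 0.00109 for early auxin response. It was 0.00375 for iron deficiency, 0.0247 for break repair and 0.0481 for root hair, so fry kept the calls of all these lists. The fry adjusted p was 0.251 for G2 and M phase, 0.0446 for cyclin-dependent kinase inhibitors and 0.0385 for stem cell niche genes. Without the count filter the camera adjusted p was 0.0455 for DNA replication and 0.602 for iron deficiency, and the cause was not tested. Leaving out 1 library gave camera adjusted p values of 0.000260 to 0.0799 for G2 and M phase (0.0799 without control replicate 3), 0.00773 to 0.337 for DNA replication (0.00773 without control replicate 1, 0.0211 without bleomycin replicate 2), 0.0217 to 0.120 for iron deficiency (0.120 without control replicate 3, 0.101 without bleomycin replicate 2) and 0.00907 to 0.793 for endodermis (0.00907 without control replicate 2). Over the alternatives other than the fit of transposable elements, genes selected for naming kept their side of the threshold in 1036 cases, lost a call in 131 and gained 1 in 3. The higher share of called genes was 45.3% to 56.3% in fits other than the test against a log2 change of 0.5, at 90.8%. Depth limited the low end, where 0 reads over the control group allow a level of up to 0.0623 CPM.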

Other observations

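The gene families and the copper transcripts below were chosen after the data were seen, and so were their tests, except the test of the 11 copper transcripts listed before their values were seen.

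Many cytosolic ribosomal protein and histone transcripts were lower in bleomycin root tips. Of 273 cytosolic ribosomal protein genes tested, 182 fell and 6 rose, with a median log2 fold change of -0.35, and of 45 histone genes 24 fell and 1 rose, with a median of -0.30. The histone genes HTB1 and HTB9 fell from 139 ± 7.39 CPM to 81.3 ± 8.68 CPM and from 250.0 ± 17.4 CPM to 164 ± 2.20 CPM (SD, n = 3 per group). WRKY transcription factor genes rose in 17 of 47 and fell in 0, NAC factor genes in 17 of 49 and 0, expansin genes in 9 of 19 and 1, and class III peroxidase genes in 10 of 35 and 0. The gene lists of the report also hold 2 of these expansin genes (root hair list, both rose), 6 of the NAC genes, NAC044 and NAC085 among them, and 1 of the peroxidase genes (endodermis list, not called), so the families are not fully separate from the lists. WRKY48 rose from 0.867 ± 0.340 CPM to 32.0 ± 1.26 CPM, and NAC103 rose from 1.15 ± 0.301 CPM to 38.1 ± 0.957 CPM (SD, n = 3 per group). Among 15 families taken from product names, Fisher's exact test against the 18777 tested genes with a product, adjusted over 30 tests, gave an adjusted p of 6.59e-111 for ribosomal proteins and 1.62e-11 for histones among genes that fell. Among genes that rose it gave 1.61e-05 for WRKY, 2.60e-05 for NAC, 2.26e-04 for expansins and 0.00934 for peroxidases, where genes of a family are not independent. RING/U-box genes (35 of 205 rose) and ERF/AP2 factor genes (15 of 74 rose, 6 fell) passed too, at 0.0129 and 0.0278, but not without control replicate 1, at 0.518 and 0.140. RING/U-box genes also lost it without control replicate 2, control replicate 3, bleomycin replicate 1 or bleomycin replicate 3, and ERF/AP2 genes with the block, at 0.127, and without control replicate 2, control replicate 3, bleomycin replicate 2 or bleomycin replicate 3. The other 6 enrichments held under both other scalings, with the block and without any 1 library, while the number of ribosomal protein genes that fell was 84 without bleomycin replicate 1 and 102 without bleomycin replicate 2, and 18 peroxidase genes rose with the block.

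Copper-handling transcripts moved together, as noted among the largest changes and then extended. FSD1, the iron superoxide dismutase gene, rose from 13.6 ± 1.84 CPM to 650.4 ± 73.6 CPM, while the copper/zinc forms fell, and CITF1, a transcription factor gene of copper uptake, rose from 0.834 ± 0.103 CPM to 28.9 ± 2.04 CPM (SD, n = 3 per group). The transporter genes YSL2, ZIP2 and COPT1 rose by 3.69 ± 0.18, 1.63 ± 0.10 and 1.13 ± 0.12 (SE), the copper chaperone gene CCH by 1.68 ± 0.12 (SE) and the reductase gene FRO4 by 5.07 ± 0.22 (SE). MIR857, another copper-regulated microRNA precursor gene, had 0 reads in the controls and was at least 26.9-fold higher with bleomycin. Of the microRNA target genes listed to fall, the 2 laccase genes that passed the count filter, LAC3 and LAC13, measured 0.17 ± 0.46 and -0.39 ± 0.18 (SE) and did not pass the test. The 7 rises held under both other scalings, with the block and without any 1 library.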
